A study of Caenorhabditis elegans with 8 samples.

How the data were processed

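The samples were oocytes of Caenorhabditis elegans collected on day 8 from 2 genotypes. One genotype carried sma-2(e502) together with fem-1(hc17) and is called the double mutant here, and the other carried fem-1(hc17) alone. sma-2 encodes a Smad protein of the Sma/Mab branch of TGF-beta signalling, and fem-1 is needed for the male fate, so that animals without its function make no sperm of their own. Total RNA was extracted with the Qiagen RNeasy kit, per the labels' protocols. Each of 8 two-colour Agilent arrays carried double mutant RNA in one dye and fem-1 RNA in the other. The double mutant was in Cy5 on 3 arrays (1, 5 and 8) and in Cy3 on 5 arrays (2, 3, 4, 6 and 9), per the labels. The labels named 6 collections of double mutant oocytes and 7 of fem-1 oocytes, so that some collections were hybridised to more than 1 array. Arrays 4 and 6 shared a double mutant collection, arrays 8 and 9 shared another, and arrays 2 and 4 shared a fem-1 collection, which left 5 linked sets of arrays. Every fem-1 collection was made before every double mutant collection, so genotype and time of collection cannot be told apart. The arrays lay on 3 slides and were scanned on the same day. Slide 1 held arrays 1 to 4, slide 2 held arrays 5, 6 and 8, and slide 3 held array 9.

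The authors deposited the scanner output of each array, made with Agilent Feature Extraction 9.5.3.1 per the file headers. Its mean and background signals are intensity values on a linear scale, before background correction and dye normalization, per the file headers. Its log ratio is the log10 of processed Cy5 over processed Cy3 signal, per the file headers, after Agilent's own background and dye corrections, and was listed at 0 for a share of the dim spots. The authors also deposited a table of log2 values, which equalled the log10 ratios turned to log2 and oriented as double mutant over fem-1, within 0.0005 on every array. Scale and direction of that table were therefore settled, and its column medians lay between 0 and 0.063.

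Each array held 44381 spots, of which 42964 were not controls and represented 20401 probes. Gene names on the array are sequence names. Through locus tags, 19057 probes were matched to 18124 genes of the WBcel235 RefSeq annotation, and 1344 probes kept the name on the array. The array's own genome build is not given in the sources used here, so no coordinates are given and the annotation served only for names and for which genes neighbour each other.

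Computation used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8). Mean signals were corrected with normexp (offset 50) against the background medians, and each array was normalized by loess with a span of 0.3 in which control spots and spots flagged as outliers had no weight. Flagged spots were then left out and saturated spots were kept. Ratios were turned to double mutant over fem-1, and duplicate spots were averaged. A probe was tested when it was well above background in either genotype's channel on at least 4 arrays and had at least 6 ratios. Of 16779 such probes, the brightest of each gene represented it, giving 15958 genes. Among 723 genes with more than 1 such probe, 16 had probes called in opposite directions. The limma fit had a genotype term and a dye term, with the linked set of arrays as a random block (consensus correlation 0.0233), followed by empirical Bayes moderation and Benjamini-Hochberg adjustment over genes, with a threshold of 0.05. With so small a correlation, the fit treated the arrays almost as independent. Values are log2 ratios with their moderated standard errors over 8 arrays unless another number is given, and every adjusted p of a gene comes from this limma fit.

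Before the data were examined, 26 gene lists were fixed, of which 18 named processes and 8 named yolk proteins or markers of other cells that an oocyte sample could hold. Of 660 genes listed by name, 623 were on the array. Lists were tested against all other genes with limma's competitive test on moderated statistics (cameraPR, preset correlation 0.01, two-sided), adjusted over the 26 lists, with an estimated correlation as an alternative. That alternative also used only 4 residual degrees of freedom, the fewest of any gene. A call lost in it can therefore not be credited to correlation alone. The rotation test fry was also run, which tests a list against no change and not against other genes. The genes named in the text followed a rule fixed at the same time. They were the 12 highest and the 12 lowest effects among called genes with the same sign on every array, up to 4 members with the smallest p of each list, all tested members of the Sma/Mab list, and fem-1. Neighbouring genes and other genes outside this rule are said to be chosen after their values were seen.

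The procedure was tested on simulated data for 15909 genes with the residual spread of the real genes, a dye effect and 200 changed genes. Over 5 simulations of this comparison without shared collection effects, 78.8% of the genes changed by a log2 of 0.5 and 96.2% of those changed by 1 were called, and 6.22% of the calls were false. When 50% of the variance came from shared collections, the shares were 78.2% and 95.4%, with 5.96% false calls. A first run with 1 simulation per setting had given 4.37% and 10.4% false calls, and the number was raised after these were seen. The simulated noise was independent between genes and equally large on every array. In the real data, estimated array weights ran from 0.18 (array 6) to 17.6 (array 4), and residuals of array pairs correlated across genes from -0.787 to 0.676. The shares of false calls need therefore not hold for the real data.

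Alternatives covered background correction, normalization within and between arrays, the deposited log2 values, the filter on dim probes, flagged spots, the dye term, the block, array weights, moderation, the slide as a block, the gene summary and leaving out each array or linked set. Where an alternative left too few linked sets to estimate the correlation (without arrays 2, 4 and 6, without arrays 6, 8 and 9, and slide 1 alone), the value of 0.0233 was used. Leaving out saturated spots, leaving out arrays 6, 8 and 9, and fitting slides 1 and 2 separately were chosen after seeing the data. For arrays, the number of arrays limits the precision. The labels name separate collections but do not say how animals were shared between them, so p-values measure the spread between these collections and arrays. Spike-in and other control spots were used in no comparison between genotypes.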

Results

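Transcript levels were compared between day 8 oocytes of the double mutant (sma-2 and fem-1) and of fem-1 alone, under a series title about reproductive aging. Each of the 8 arrays compared both genotypes directly. Between 70.1% and 87.7% of spots were well above background in the double mutant channel, and between 64.7% and 77.1% in the fem-1 channel. In Cy5, between 94 and 424 spots per array were saturated, against 0 to 78 in Cy3. Ratios of different arrays correlated across genes with a median Pearson's r of 0.505, from 0.0703 (arrays 6 and 8) to 0.914 (arrays 2 and 4). These r are across genes, which are not independent replicates.

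The first question was which transcripts differed between the genotypes. The highest ratio in the double mutant was that of ppm-1.G, a protein phosphatase gene, which was 6.08-fold higher (log2 2.60 ± 0.13 SE, n = 8, adjusted p = 4.68e-05). odc-1, which encodes the polyamine enzyme ornithine decarboxylase, rose by a log2 of 1.76 ± 0.38 (adjusted p = 0.0113), and zip-2, a bZIP transcription factor gene, by 1.52 ± 0.20. The lowest ratios were those of C17F4.7 (log2 -3.68 ± 0.41, adjusted p = 0.000771) and the collagen gene col-71 (log2 -3.18 ± 0.20, adjusted p = 0.000111). Both lie in the block of lower genes on chromosome II described below. There, sequence differences under the probes, labelling by transcripts of related genes and fewer copies of the region were not excluded. By the rule that selected them, all of these genes had the same sign on each of the 8 arrays.

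Other genes that rose on every array included cam-1, a Ror receptor tyrosine kinase gene (1.47 ± 0.08), the aquaporin gene aqp-2 (1.43 ± 0.28), icmt-1, which encodes an isoprenylcysteine methyltransferase (1.34 ± 0.22), and epi-1, a laminin alpha gene (1.26 ± 0.19). The sequence-named genes Y15E3A.5 (1.74), Y58A7A.4 (1.64), C49G7.7 (1.38), F56D2.5 (1.26) and Y57G11C.20 (1.26) completed the 12 highest. Among those that fell on every array were ule-5 (-2.26 ± 0.43) and ule-4 (-2.23 ± 0.27), named for expression in the uterine lumen, the infection response gene irg-8 (-2.02 ± 0.30) and dod-19 (-2.001 ± 0.27), named as a gene downstream of DAF-16. C44B7.5, Y37D8A.19, Y62H9A.4, Y62H9A.3, kola-4 and B0511.11 made up the rest of the 12 lowest, between -2.23 and -2.06. Whether RNA of other cells in the samples contributed to the ratios of the 12 lowest genes was not tested. ule-5 (sequence name Y62H9A.6) ends a run of lower neighbours on the X chromosome described below, and Y62H9A.4, Y62H9A.3 and kola-4 are also X-linked. Of the 24 highest and lowest genes, 10 lost their call after scale normalization and 9 without arrays 2, 4 and 6. Within slide 1 the call was lost for 3 of them, and within slide 2 for all 24.

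**Figure D1:**
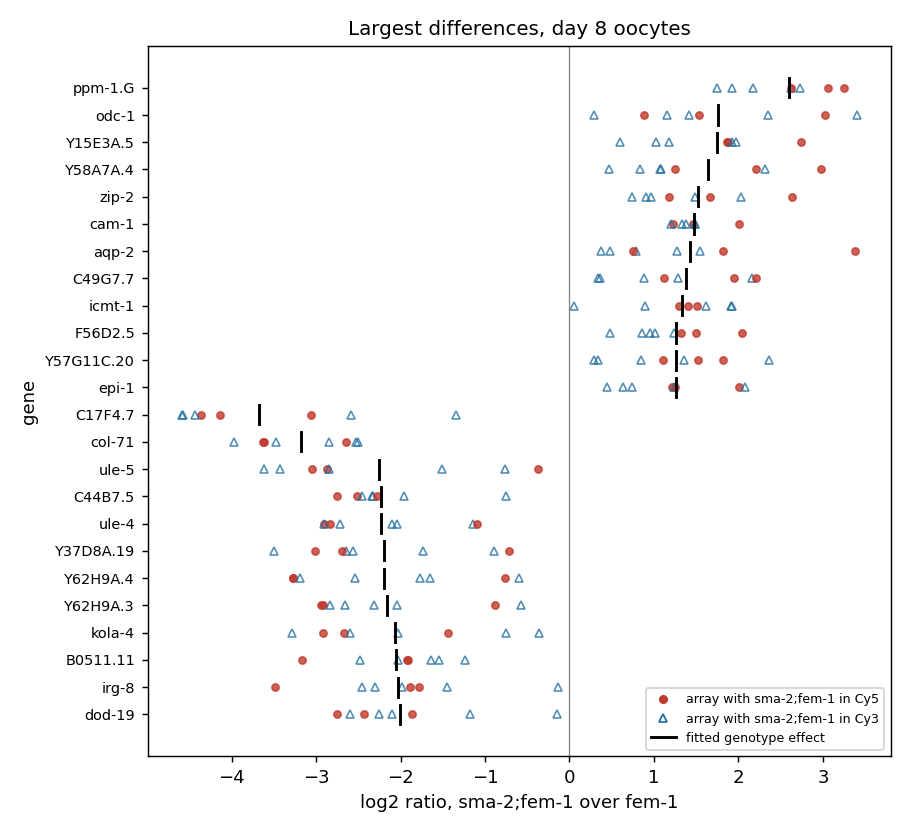
The horizontal axis gives the log2 ratio of the double mutant over fem-1 and the vertical axis the 12 highest and 12 lowest called genes with the same sign on all arrays; circles and triangles are single arrays by dye orientation, and black bars are fitted effects. The fitted effects run from 2.60 for ppm-1.G to -3.68 for C17F4.7, and every array lies on the same side of 0 within a gene, as the selection required.

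In all, 4823 of 15958 genes (30.2%) had an adjusted p under 0.05 in the limma fit, 2409 higher and 2414 lower in the double mutant, and 11135 did not pass. Most of these differences were small, with a median absolute log2 of 0.276. A change of at least 1.5-fold was found in 231 higher and 407 lower genes, and one of at least 2-fold in 34 higher and 134 lower genes. Of the 4823 genes, 2931 had the same sign on all arrays. The count fell to 2941 when linked sets were averaged first, to 1474 without the linked set of arrays 2, 4 and 6, and to 1449 after scale normalization. With the slide as a random block it was 3837, within slide 1 it was 6555, and within slide 2, with 3 arrays, limma called 0 genes while 3832 had an unadjusted p under 0.05.

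The sma-2 transcript itself was measured first among the pathway genes. Its log2 ratio was -0.16 ± 0.05 (adjusted p = 0.0531), below 0 on 7 of 8 arrays, and it did not pass the threshold over all genes. The labels do not say whether the e502 allele alters the transcript level, so this value checks no label. fem-1, which is mutant in both genotypes, was higher by 0.15 ± 0.03 (adjusted p = 0.00869, 7 of 8 arrays), and by 0.30 as the mean over its probes.

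Of 13 tested members of the Sma/Mab list, 4 were higher, 0 were lower and 9 did not pass over all genes. Adjusted over the list alone, 4 were higher and 1 was lower, which was sma-2 itself. The 4 higher genes were daf-4, the type II receptor gene (0.41 ± 0.06, and 0.21 as the mean over its probes), unc-40, a netrin receptor gene also placed in this pathway (0.40 ± 0.03), lon-2, a glypican gene (0.35 ± 0.09, a call lost in 10 of 33 alternatives), and kin-29, a salt-inducible kinase gene (0.22 ± 0.03). The type I receptor gene sma-6 had -0.03, the Smad genes sma-3 and sma-4 had 0.10 and -0.10, sma-9 had 0.12, sma-10 had 0.14, lon-1 had 0.20, mab-31 had -0.04 and the ligand gene tig-2 had -0.03. As a list the pathway did not pass the competitive test (median log2 0.12, adjusted p = 0.106, and adjusted p = 0.737 with an estimated correlation). The rotation test fry, which tests against no change and not against other genes, called it as higher (fry, adjusted p = 0.00908).

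The second question was which processes moved together. Of 42 cell cycle regulators, 18 were higher, 7 lower and 17 not past the threshold (19 and 8 adjusted over the list alone). cdk-4, the G1 kinase gene, rose by 0.83 ± 0.05 (adjusted p = 0.000117), and the B-type cyclin genes cyb-3 and cyb-1 rose by 0.52 ± 0.04 and 0.41 ± 0.04, where cyb-1 was saturated on the 3 arrays with the double mutant in Cy5. efl-1, an E2F-like factor gene, rose by 0.32 ± 0.03. The list passed (median log2 0.06, above 0 on 7 of 8 arrays, adjusted p = 0.0244) but not with an estimated correlation (adjusted p = 0.737 with an estimated correlation), and the call was lost in 10 of 35 alternatives.

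Of 13 condensin and dosage compensation genes, 8 were higher, 0 lower and 5 not past the threshold, with the same counts adjusted over the list alone. sdc-3 and dpy-26, both needed for dosage compensation, rose by 0.38 ± 0.06 and 0.36 ± 0.05, and the condensin subunit genes capg-2 and hcp-6 by 0.21 ± 0.04 and 0.18 ± 0.03. The list's median log2 was 0.20, above 0 on all 8 arrays (adjusted p = 0.0238, and adjusted p = 0.737 with an estimated correlation), and the call was lost in 3 of 35 alternatives. Of 23 apoptosis and engulfment genes, 8 were higher, 1 lower and 14 not past (9 and 1 adjusted over the list alone). The nuclease gene crn-4 rose by 0.69 ± 0.05, the caspase gene ced-3 by 0.64 ± 0.08 (higher on 7 of 8 arrays), the engulfment receptor gene ced-1 by 0.54 ± 0.05 (0.27 as the mean over its probes) and ced-5 by 0.47 ± 0.06. That list's median log2 was 0.09, above 0 on all 8 arrays (adjusted p = 0.00987, and adjusted p = 0.347 with an estimated correlation). Its estimated correlation of 0.0082 lay below the preset 0.01, so this lost call came with the fewer degrees of freedom.

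Among 44 oocyte and maternal factors, 21 were higher, 7 lower and 16 not past (23 and 7 adjusted over the list alone). lin-41, a regulator of oocyte maturation, rose by 0.46 ± 0.06, and par-3, a polarity gene, by 0.44 ± 0.06. fbf-1, a Pumilio family gene that maintains germline stem cells, fell by 0.41 on the log2 scale. perm-2, needed for the eggshell's permeability barrier, had -1.35 ± 0.09, with a saturated Cy5 spot on all 8 arrays. The list's median log2 was 0.19, above 0 on 7 of 8 arrays (adjusted p = 0.0400, and adjusted p = 0.799 with an estimated correlation), and the call was lost in 8 of 35 alternatives.

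In 3 further lists that passed, more members were lower than higher. Ribosomal protein genes had 0 higher, 55 lower and 6 not past of 61 tested (0 and 56 adjusted over the list alone), with a median log2 of -0.65, below 0 on all 8 arrays (adjusted p = 3.44e-59, and adjusted p = 0.235 with an estimated correlation). rpl-30 had -0.99 ± 0.06, rpl-32 -0.94 ± 0.05, rps-21 -0.83 ± 0.03 and rps-23 -0.82 ± 0.04, with saturated spots on 8, 8, 7 and 8 arrays, so these values are not exact. At least 1 saturated spot was present for 51 of the 61 genes, and over genes and arrays saturation occurred 335 times in Cy5 and 64 times in Cy3. The list's median was between -1.101 and -0.998 on the arrays with the double mutant in Cy5 but between -0.37 and -0.13 on the others. The 10 members with no saturated spot had a median of -0.09, with 4 lower and 0 higher. With saturated spots left out, an alternative chosen after seeing the data, the list's median was -0.27 and it no longer passed (adjusted p = 0.0525). At least 6 ratios were still required there, and 42 members had been saturated on at least 4 arrays. Fewer members were therefore tested, without rpl-30, rpl-32, rps-21 and rps-23, so that median describes a smaller and less saturated part of the list.

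**Figure D2:**
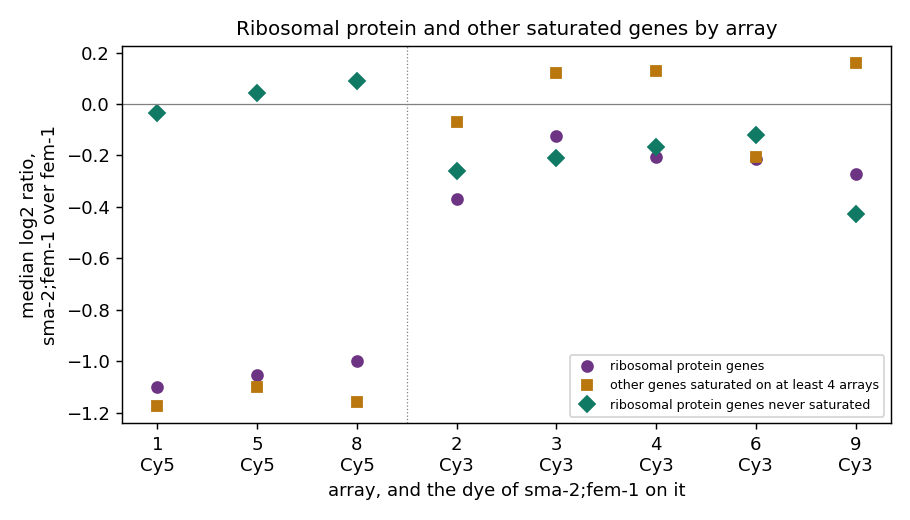
The vertical axis gives the median log2 ratio of the double mutant over fem-1 per array, and the horizontal axis the array with the dye of the double mutant. Ribosomal protein genes lie between -1.101 and -0.998 on the arrays with the double mutant in Cy5, close to other genes saturated on at least 4 arrays, and between -0.37 and -0.13 on the arrays with it in Cy3, where those other genes lie between -0.20 and 0.16.

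Of 35 genes of the mitochondrial respiratory chain, 13 were lower, 4 higher and 18 not past (15 and 4 adjusted over the list alone). The ADP/ATP carrier genes ant-1.4 and ant-1.3 fell most, with -1.44 ± 0.11 and -1.43 ± 0.11, and are close paralogs that one transcript could label together. atp-4, which encodes an ATP synthase subunit, had -0.42 ± 0.05, and clk-1, needed for ubiquinone synthesis, had -0.41 ± 0.04. The list's median log2 was -0.08, below 0 on all 8 arrays (adjusted p = 0.0112, and adjusted p = 0.737 with an estimated correlation), and it was 0.0529 after median centring in place of loess. Of 41 meiotic synapsis and recombination genes, 14 were lower, 5 higher and 22 not past (17 and 6 adjusted over the list alone). The chromosome axis genes him-3 and htp-1 had -0.40 ± 0.04 and -0.34 ± 0.03, the crossover gene zhp-3 had -0.40 ± 0.04 and the nuclear envelope gene sun-1 had -0.29 ± 0.04. That list's median log2 was -0.11, below 0 on all 8 arrays (adjusted p = 0.0244, and adjusted p = 0.799 with an estimated correlation). It was 0.0496 after median centring, and the call was lost in 14 other alternatives.

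The remaining 11 process lists did not pass the competitive test, the Sma/Mab list included. Members moved in both directions in most of them. Of 52 chromosome segregation genes, 16 were higher and 10 lower (17 and 11 adjusted over the list alone, adjusted p = 0.371), among them zyg-9 (0.72 ± 0.06), zen-4 (0.53 ± 0.05), csc-1 (0.44 ± 0.03) and the securin gene ify-1 (-0.62 ± 0.05). Of 41 DNA damage and repair genes, 13 were higher and 4 lower (18 and 7 adjusted over the list alone, adjusted p = 0.137), with the mismatch repair gene mlh-1 at 0.56 ± 0.03 and the p53 homolog gene cep-1 at -0.39 ± 0.07. Of 40 DNA replication genes, 10 were higher and 6 lower (12 and 6 adjusted over the list alone, adjusted p = 0.499), with mcm-7 at 0.43 ± 0.06 and the geminin gene gmn-1 at -0.38 ± 0.03. Of 25 chromatin and germline fate genes, 7 were higher and 4 lower (7 and 5 adjusted over the list alone, adjusted p = 0.267), with the methyltransferase gene mes-4 at 0.60 ± 0.05 and the demethylase gene spr-5 at 0.53 ± 0.04.

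P granule and small RNA genes split into 9 higher and 8 lower of 28 (9 and 8 adjusted over the list alone, adjusted p = 0.226). Both pgl-1 (-0.55 ± 0.04) and glh-1 (-0.63 ± 0.06), which encode core P granule proteins, were lower, and glh-1 had saturated spots on 7 arrays. Of 24 heat shock and unfolded protein genes, 3 were higher and 7 lower (4 and 7 adjusted over the list alone, adjusted p = 0.195), with hsp-16.2 at -0.64 ± 0.08 and hsp-4 at -0.37 ± 0.03. Of 23 oxidative stress genes and DAF-16 targets, 1 was higher and 4 were lower (1 and 4 adjusted over the list alone, adjusted p = 0.550). That higher gene was daf-16 itself (0.36 ± 0.04, and 0.20 as the mean over its probes), and fat-5, a fatty acid desaturase gene, had -0.93 ± 0.19. Of 26 innate immunity genes, 3 were higher and 8 lower (3 and 9 adjusted over the list alone, adjusted p = 0.184). The infection response genes irg-2 and irg-1 rose by 1.25 ± 0.20 and 0.68 ± 0.09 while the lysozyme gene lys-1 had -0.49 ± 0.07, and the list's median was -1.13 on array 6, against -0.34 to 0.21 on the others. Of 33 proteasome genes, 6 were higher and 9 lower (8 and 11 adjusted over the list alone, adjusted p = 0.3496). Their median of 0.02 and mean of -0.04 differed in sign, and after median centring the list passed in the other direction (median 0.26). Of 38 histone genes, 7 were higher and 3 lower (7 and 2 adjusted over the list alone, adjusted p = 0.229), with the linker histone gene his-24 at 0.89 ± 0.18. The DNA replication list also differed in sign between its median (-0.00029) and its mean (0.03).

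**Figure D3:**
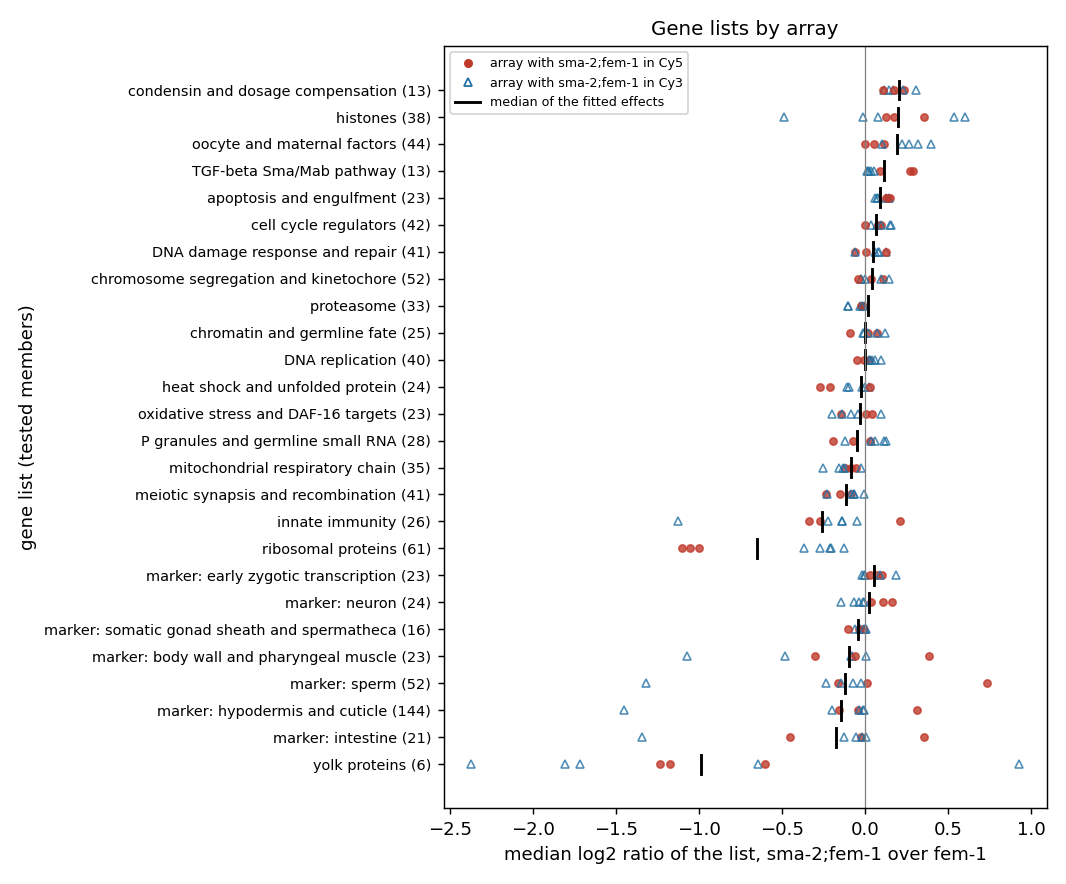
The horizontal axis gives the median log2 ratio of each gene list, double mutant over fem-1, and the vertical axis the lists with their tested members; circles and triangles are single arrays by dye orientation and black bars are medians of the fitted effects. Yolk proteins have the lowest fitted median (-0.99) and ribosomal proteins the lowest among the process lists (-0.65).

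The third question was whether markers of other cells differed between the samples. Somatic gonad transcripts gave single strong differences. The sheath innexin genes inx-9 and inx-8 fell by 1.38 and 0.84 on the log2 scale, on all 8 arrays, and nhr-6, needed for spermatheca development, rose by 0.36 ± 0.05. Both innexin genes bear neighbouring sequence names (ZK792.3 and ZK792.2), and whether 1 transcript labelled both probes was not tested. Yolk protein genes had a median of -0.99, with vit-6 at -1.53 ± 0.41 (adjusted p = 0.0271, and -0.85 as the mean over its probes) and vit-1 at -1.18 ± 0.28 (adjusted p = 0.0176). Their proteins are made in the intestine and taken up by oocytes, while the arrays measured RNA. vit-3 had -1.09 and vit-2 had -0.88, and neither passed. On array 9 alone the yolk median was above 0 (0.93), and without that array the yolk list passed (median -1.26, adjusted p = 0.00203). Without arrays 2, 4 and 6 its median was -0.42 (adjusted p = 0.399), and over all arrays it had adjusted p = 0.815 with an estimated correlation.

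In limma's competitive test 0 of the 8 marker lists passed and 0 had an unadjusted p under 0.05. The test fry, against no change and not against other genes, called 1 of them, the sheath and spermatheca list (adjusted p = 0.0105, median -0.04). It also called 10 process lists. Among these were the Sma/Mab list (fry, adjusted p = 0.00908, higher), the DNA damage list (fry, adjusted p = 0.0368, higher) and the heat shock list (fry, adjusted p = 0.0315, lower). These had not passed the competitive test. Yolk proteins had 0 higher and 2 lower of 6 (0 and 3 adjusted over the list alone, adjusted p = 0.142), and sheath and spermatheca markers 1 higher and 2 lower of 16 (1 and 2 adjusted over the list alone, adjusted p = 0.184). Intestine markers had 1 higher and 2 lower of 21 (1 and 2 adjusted over the list alone, adjusted p = 0.273), with the fatty acid binding protein gene lbp-6 at -1.28 ± 0.19. Muscle markers had 1 higher and 4 lower of 23 (1 and 4 adjusted over the list alone, adjusted p = 0.267), with unc-27 at -1.06 ± 0.26 and unc-87 at -0.78 ± 0.16. Cuticle and hypodermis markers had 5 higher and 9 lower of 144 (5 and 8 adjusted over the list alone, adjusted p = 0.184), with dpy-10 at 0.94 ± 0.09 and dpy-9 at -0.83 ± 0.10. Sperm markers had 4 higher and 5 lower of 52 (4 and 4 adjusted over the list alone, adjusted p = 0.3496), with spe-41 at 0.70 ± 0.10 and spe-15 at -0.59 ± 0.08. Neuron markers had 3 higher and 2 lower of 24 (2 and 2 adjusted over the list alone, adjusted p = 0.796), with a median of 0.03 and a mean of -0.0056. Early zygotic genes had 3 higher and 2 lower of 23 (3 and 2 adjusted over the list alone, adjusted p = 0.3496), with ceh-51 at 0.94 ± 0.14 and end-3 at -0.33 ± 0.05.

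The median ratios of sperm, cuticle, muscle and intestine markers were each lowest on array 6 and highest on array 8. On array 6 their median log2 ratios were -1.32, -1.45, -1.07 and -1.34, and on array 8 they were 0.73, 0.31, 0.38 and 0.35. Without arrays 6, 8 and 9, an alternative chosen after seeing the data, 5826 genes differed and the yolk, intestine and cuticle lists passed as lower (medians -1.25, -0.19 and -0.06). In that fit 9 process lists passed, against 7 over all arrays. The DNA damage (0.07), heat shock (-0.15) and innate immunity (-0.21) lists were added and the meiotic list (-0.06) was lost.

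The dye and the sharing of collections were examined as features of the design. The dye term was called for 209 genes in the limma fit, against 4823 for genotype. The 3 pairs of arrays that shared a collection had residuals correlating across genes with r of 0.676 (arrays 2 and 4, shared fem-1 collection), -0.707 (arrays 4 and 6, shared double mutant collection) and 0.215 (arrays 8 and 9, shared double mutant collection). Their mean lay 0.208 above that of the 25 other pairs. Arrays 2 and 6, in the same linked set but with no shared collection, had -0.497, so residual correlations of both signs occurred within that set. The fit's small consensus correlation was not stable, at -0.150 without array 2 and 0.488 without array 6. It therefore does not show that shared collections had no effect. Without the block 4940 genes were called, so the block changed the count little.

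Genes that neighbour each other on chromosome II were lower together, an observation made after the values were seen. In the order of the WBcel235 annotation, 36 bright genes (average log2 intensity of at least 9) from C17F4.7 to Y14H12B.1 included 27 lower, 1 higher and 8 not past the threshold, with a median log2 of -0.68. Of the 96 dimmer genes between them, 29 were lower and 3 higher. The ends of the block were set at its outermost lower genes in these same ratios, which favours a high share of lower genes. Next to C17F4.7, the genes fbxc-50 (-0.21), wht-4 (-0.03) and Y46D2A.1 (-0.05) did not pass. F14D2.15, bath-30, bath-29 and bath-27 had -0.93, -0.91, -0.87 and -0.93, and C16C8.14, C16C8.12 and C16C8.11 had -1.89, -1.56 and -1.52. The splicing factor gene smu-2 had -0.88 ± 0.04 and the dynactin gene dnc-3 -0.75 ± 0.05. T06D4.1 was the exception, at 0.85 ± 0.14. The median of the block lay between -0.79 and -0.59 on each of the 8 arrays.

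**Figure D4:**
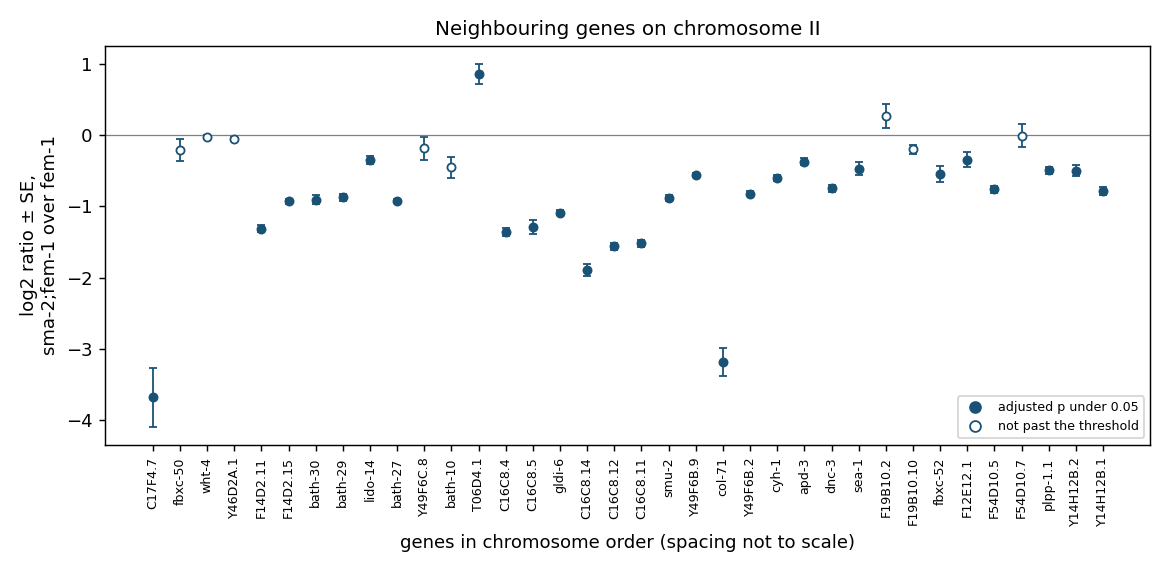
The vertical axis gives the log2 ratio of the double mutant over fem-1 with its standard error, and the horizontal axis 36 bright genes in their order on chromosome II, not to scale; filled points passed the threshold. Of the 36 genes, 27 are lower and T06D4.1 is higher.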

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

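The tests on the arrays below were chosen after the values were seen. The 8 arrays were searched for one that stood apart from the rest in 137 named genes and 26 list medians, and 9 of these 163 results had one. Chance alone singles out about 1 in 20 such groups. The rule for the spike-in probes described last was also set after their values were seen, and replaced a stricter rule that no probe met.

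Array 6 stood apart in 3 lists of markers and immune genes. The median log2 ratio of the cuticle and hypodermis list was -1.45 there, against -0.20 to 0.31 on the other arrays. The sperm list had -1.32, against -0.23 to 0.73, and the innate immunity list had -1.13, against -0.34 to 0.21.

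A candidate source on array 6 is RNA of other cells in its fem-1 collection, since all 4 lists of sperm, muscle, cuticle and intestine markers were highest there among the 8 fem-1 channels (major sperm protein genes 10.8, against 8.27 to 9.49). It stays open, since in the double mutant channel of array 6 only 3 of the 4 lists lay within the range of the other arrays (intestine 8.02, against 8.07 to 8.52), and in the fem-1 channel msp-19 was high (12.32) but the cuticle gene dpy-14 lowest (9.67, against 10.9 to 13.4), both chosen after their values were seen. The early zygotic list, whose level of 7.63 was the lowest of the 8, cannot decide about a raised background in that channel. These levels were taken after background correction and normalization, which can remove a rise of the whole channel. The measured median Cy5 background of array 6, where fem-1 was in Cy5, was 34, against 33 to 37 on the other arrays. Sperm RNA throughout the double mutant collection on array 8 is argued against by array 9, labelled with the same collection, whose major sperm protein level was 1.497 lower, but the labels do not say whether its portions were extracted separately, so sperm RNA in the portion on array 8 (10.0, against 7.83 to 8.68 on the other arrays) stays open. Genes chosen after their values were seen went both ways, since act-4 (13.1 and 13.2), cpz-1 (12.5 and 13.1) and asp-1 (14.4 and 14.6) were highest on arrays 8 and 9 among the double mutant channels, while the muscle genes mlc-1 (12.1 and 10.4) and lev-11 (11.1 and 10.1) were high on array 8 alone.

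Array 8 was highest for 3 genes, cam-1 (2.00, against 1.20 to 1.48), cdk-4 (1.28, against 0.57 to 0.88) and lon-2 (0.91, against 0.03 to 0.40). C44B7.5 was least negative on array 3 (-0.75, against -2.76 to -1.96). rnr-1, a ribonucleotide reductase gene, was lowest on array 5 (0.10, against 0.35 to 0.51), where its double mutant signal was saturated, as on array 8, and its fitted ratio was 0.42 with saturated spots left out. atp-4 was lowest on array 2 (-0.74, against -0.48 to -0.27).

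In Cy3, the 10 adenovirus E1A spike-in probes, which entered no comparison, lay above the median of the negative controls on all 8 arrays. Their smallest log2 excess over the arrays was 0.46, 0.38, 0.42, 0.36, 0.36 and 0.28 for r60_1, r60_3, a107, a20, n11 and a22, and 0.098, 0.056, 0.044 and 0.037 for a97, a104, a135 and n9. Whether spike-in RNA was added is not given in the sources used here.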

How the results depend on the processing

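Settings for slides 1 and 2, for saturated spots and for arrays 6, 8 and 9 were chosen after seeing the data. Against 4823 differing genes, 1449 were called after scale normalization, 2941 with linked sets averaged, which leaves 5 values, 638 at 1.5-fold or more and 0 within slide 2, which has 3 arrays. Leaving out single arrays or linked sets gave 1474 to 4972 genes, the lowest without arrays 2, 4 and 6, and the cause was not tested beyond the fewer arrays. For the dye effect, 209 genes were called, against 88 without background correction and 11489 after median centring, which removes no trend with intensity. Of the process lists, 7 passed, against 12 after median centring, 4 with array weights and 0 with an estimated correlation and its 4 residual degrees of freedom, where 2 of the 26 lists had an unadjusted p under 0.05. Without single arrays or linked sets, 3 to 9 passed, the lowest without array 6. Of the marker lists, 0 passed, against 5 with Agilent's log ratio, 5 with the deposited log2 values, 5 within slide 2, 3 after scale normalization, 3 without arrays 6, 8 and 9, and 2 each after median centring, without the dye term, with linked sets averaged and within slide 1, and 0 to 2 without single arrays or linked sets. The sma-2 ratio of -0.16 passed without background correction (-0.20), with array weights (-0.16), within slide 1 (-0.24) and without array 5 (-0.22), and ranged from -0.22 to -0.11 without single arrays or linked sets. After median centring, spl-1 turned to 0.0253, the respiratory chain list to 0.0529, the meiotic list to 0.0496 and the proteasome list to 0.26. The cause of these changes was not tested. Of 124 called named genes, 123 kept their sign under each alternative in which they were tested (116 with saturated spots left out and 123 with the strict filter on dim probes), and calls were lost for 74 after scale normalization, 43 without arrays 2, 4 and 6, 27 after median centring and 124 within slide 2. Their values moved by over 1.5 times for 45 after median centring, 23 with Agilent's log ratio, 11 without background correction and 5 when probes of a gene were averaged. Some alternatives could not change a sign, since normalizing only intensities between arrays, dropping moderation and moderating by intensity leave the ratios as they are. The deposited log2 values repeat Agilent's log ratio and are no separate check. Saturation in Cy5 limits the brightest genes, of which 230 had a saturated spot, and dim spots near background limit the rest.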

Other observations

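Tests on shuffled gene order, on probe matches, on saturated genes outside the ribosomal list and on other assignments of the genotypes were set before their results were seen, and the patterns themselves, the test on copies of the region, the assignments that turned whole linked sets and the comparison of chromosomes were chosen after. Also after first results, resamples of the permutation test on saturated genes were raised from 10000 (permutation test, two-sided, p = 0.0023) to 100000. The value for bright unsaturated genes became a count because there were 0 such genes, and a block of 10 genes inside the block of 36 on chromosome II was merged into it, which left the 36 genes as they were.

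X-linked genes differed from autosomal genes in the balance of directions. Among 2014 tested X-linked genes, 372 were higher and 134 lower in the double mutant (73.5% higher), while autosomal genes had 1894 higher and 2187 lower (46.4% higher, odds ratio 3.20, Fisher's exact test, two-sided, p = 1.92e-31, adjusted p = 1.15e-30 over 6 tests). Genes are not independent replicates, so this p describes these genes only. In 5 bins of rising intensity, the share of higher X-linked calls was 69.2%, 70.4%, 76.3%, 75.8% and 47.4%, against 51.3%, 48.5%, 44.2%, 42.4% and 49.3% of autosomal calls. The odds ratio was 1.62 without arrays 6, 8 and 9, 1.58 within slide 1 and 1.52 after median centring, and 4.86 without arrays 2, 4 and 6. The median log2 ratio of all tested X-linked genes was 0.0242, against 0.00192 for autosomal genes.

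Lower ribosomal protein ratios may come in part from saturated Cy5 spots, on the arrays with the double mutant in Cy5. The 49 genes outside the list that were saturated on at least 4 arrays had a median log2 of -0.62, close to the -0.74 of the 42 ribosomal protein genes so saturated, within the bound of 0.3 set beforehand. The difference of 0.12 was rarely reached when these genes were shuffled (permutation test, two-sided, p = 0.0014). Genes are not independent replicates, so that p describes these genes only and not the spread between arrays. The difference between dye orientations of the 49 genes outside the list was -1.18, against -1.24 for the ribosomal protein genes. This fits saturation as the source of the larger shift on arrays with the double mutant in Cy5. On the 5 arrays with the double mutant in Cy3, saturated Cy5 spots would cap the fem-1 signal and raise the ratio. Yet the list's median was below 0 on each (-0.37 to -0.13), as was that of its never saturated members (-0.43 to -0.12). The 49 genes lay between -0.20 and 0.16 there. These values argue against saturated Cy5 spots as the source on those 5 arrays. On the other arrays, the never saturated members had -0.03, 0.04 and 0.09. Normalization of bright spots was not separable from saturation, since 0 unsaturated genes outside the list were as bright. Saturation leaves out the 10 members never saturated, of which 4 were lower and 0 higher, so a lower level in the double mutant stays open and untested as a part, and genotype and time of collection cannot be told apart.

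The block of lower genes on chromosome II is unlikely to be a chance order, since a window of 15 bright genes as extreme as its mean of -1.07 appeared in a share of 0.0001 of shuffled orders, the smallest that 10000 shuffles can give. Among the lower genes, 7.41% had a probe matching that of another over at least 50 bases at 85% identity. Probes were not compared with transcripts, so labelling of a probe by transcripts of related genes stays open. Fewer copies of the region in the double mutant stay open, since the 75% of its bright genes that were lower had been counted before a bound was set, and lower genes set the ends of the block. Sequence differences under the probes, as between strains of different descent, also stay open, along with regulation by genotype, which was not tested. Only 2 of the 27 lower genes had more than 1 tested probe, and although their probes differed by at most 0.22, which argues against such differences in these genes, they are too few to speak for the others. A second run of lower neighbours lay on the X chromosome, from F54F7.2 to ule-5, with 5 lower and 1 higher of 9 bright genes and a median of -1.75.

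Chance was excluded as the origin of the number of differing genes only when arrays are taken as independent. With the genotypes reassigned to the channels of single arrays, 1 of 100 assignments, the real one, gave as many genes. It gave 4794 among genes measured on all arrays, and the highest of the others gave 441. Arrays that share collections are not independent, and turning whole linked sets leaves 16 assignments, too few for a share under 0.05. Among these the real one gave 4794 genes and the highest of the others 1.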
